A study of Mus musculus with 8 samples.

How the data were processed

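Whole retinas of mice at postnatal day 7 were profiled by RNA-seq in 8 samples, 4 WT and 4 Fbxl11-CKO. Total RNA was extracted with TRIzol LS and made into libraries with a stranded TruSeq mRNA kit, per the labels' protocols. The deposited files give 1 whole-number count per gene and library with gene ID, chromosome, exon positions, strand and length, per the file headers. Reads were aligned and counted by the authors with HISAT2, SAMtools and featureCounts on GRCm38.p6, and DESeq2 was also named, per the submitters' processing notes. Tool versions, the annotation release and the strand setting of the counting are not given in the sources used here. Overlapping, antisense and near-identical genes are therefore uncertain where reads could be shared. The deposited counts were not normalized, with totals of 19607279 to 35990679 per library.

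The files list 54146 genes in the same order. Gene symbols were taken from GENCODE M21 by Ensembl ID without its version, which matched 54079 IDs. Of these, 52480 were identical with their version and had the same start and end. Coordinates are those of the files, on GRCm38. Samples were grouped by the genotype in the labels. Each library was taken as 1 replicate, as the labels number them. No pair matched within sampling noise (lowest chi-square per degree of freedom 6.2), which excludes copies of 1 library but not repeat preparations of 1 sample. The floor that 3 counts set per library lay between 0.083 and 0.153 CPM, and it covers counting error only.

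Genes were filtered with edgeR's filterByExpr, which left 19119 genes, scaled by TMM and tested with edgeR 4.0.16 (R 4.3.3) by the robust quasi-likelihood F test with genotype as the only term. P-values were adjusted by Benjamini-Hochberg over all tested genes, with 0.05 as threshold. CPM uses TMM-scaled library sizes. Gene lists were tested on voom values with limma 3.58.1 by camera, with the correlation preset at 0.01 or estimated, and by fry, adjusted over 31 lists with at least 3 tested members. The marker lists for rods, cones, photoreceptor precursors, bipolar, Müller, amacrine, horizontal and ganglion cells, progenitors, and non-neuronal cells, the lists of cell cycle, p53, kinase inhibitors, gliosis, interferon, synapse, H3K36, Polycomb, Hox, germline, immediate early, stress, Notch, Wnt, histone, mitochondrial and sex-linked genes, and all alternatives except those named as added, were fixed before the data were examined. Some genes stand in more than 1 list.

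Named genes are Kdm2a, then the 10 genes with the largest and the 10 with the lowest log2 fold change. These had adjusted p under 0.05, a mean log2 CPM of at least 1 and no overlap between genotypes, leaving out predicted gene models and symbols ending in Rik. From each list up to 2 members per direction with the lowest adjusted p were eligible, and members against a list's majority may be named. Others are marked as chosen after their values were seen.

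The alternatives were RLE and upper-quartile scaling, TMM without rod, bipolar and Müller genes, no filter or a stricter filter (CPM of at least 1 in at least 4 libraries), DESeq2 1.42.0, limma-voom, no robust estimation, a replicate block, leaving out each library, leaving out chromosomes X, Y and M, an adjusted p of 0.01 and a test against a 1.2-fold change. Added after seeing the data were a fit without the WT libraries with Xist counts and a fit with the noncoding share as a covariate. CpG content, length and GC content were compared in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. The comparison was tested on simulated data. On simulated counts for this comparison over 19119 genes, edgeR recovered 97.0% of planted 4-fold, 83.6% of 2-fold and 49.3% of 1.5-fold changes, and called 0.042% of unchanged genes. In the simulation 18894 genes were left unchanged, whereas 51.3% of the tested genes were called in the data. These rates may therefore not hold for the data.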

Results

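RNA was measured by stranded mRNA sequencing of whole mouse retina at postnatal day 7. The 4 wild-type (WT) libraries were compared with 4 libraries labelled Fbxl11-CKO, read here as a conditional knockout of Fbxl11. Fbxl11, listed in the annotation as Kdm2a, is a demethylase of histone H3 lysine 36. The series title places the gene in the development of late-born retinal cell types, which in mice are the rods, bipolar cells and Müller glia. The libraries held 19607279 to 35990679 counts assigned to genes. The labels do not say whether replicates came from separate animals, so p-values measure the spread between these libraries, which may be partly technical. WT replicates 1 and 2 and Fbxl11-CKO replicates 2 and 4 were closer to each other (chi-square per degree of freedom 6.2 and 6.4) than the other pairs within a genotype (19.6 to 50.3). WT replicates 3 and 4 held 113927 and 221895 counts of Xist, the noncoding RNA of the inactive X chromosome, and 0 counts of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty. WT replicates 1 and 2 and all 4 Fbxl11-CKO libraries held 45 to 324 counts of Xist and at least 1750 of each Y-linked gene.

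The targeted gene, Kdm2a (ENSMUSG00000054611.16, GRCm38 chromosome 19, 4314419 to 4398285, minus strand), was lower in all 4 Fbxl11-CKO libraries than in any WT library. Kdm2a stood at 182, 173, 171 and 183 CPM (library-scaled counts, TMM) in WT replicates 1 to 4 and at 135, 144, 134 and 138 CPM in Fbxl11-CKO replicates 1 to 4, or 177 ± 6.20 against 137 ± 4.47 CPM on average (SD, n = 4 each). The log2 fold change was -0.37 ± 0.07 (SE), with adjusted p = 0.00138 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The counts cover all exons of the gene and the deleted exons are not given in the sources used here, so transcripts that lack an exon still count towards this level.

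**Figure D1:**
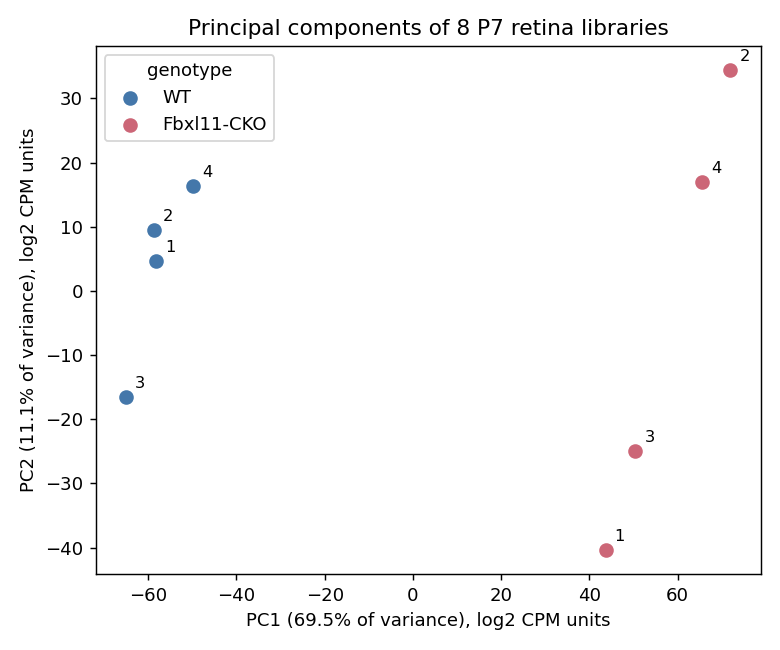
Principal components of log2 CPM over 19119 tested genes, one point per library, numbered by replicate. The first component (x axis, 69.5% of the variance) places the 4 WT libraries between -65.05 and -49.81 and the 4 Fbxl11-CKO libraries between 43.71 and 71.95, and the second (y axis, 11.1%) spreads the libraries within each genotype.

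The main comparison asked which genes differ between Fbxl11-CKO and WT retina. Of 19119 tested genes, 4988 rose and 4811 fell in Fbxl11-CKO, together 9799 genes or 51.3%. At least 2-fold changes were seen in 3231 of them, 1798 higher and 1433 lower. The deepest falls by the rule for named genes were those of Zfp518a, a zinc-finger gene, and Ccdc91. Zfp518a (chromosome 19, 40894705 to 40917947) went from 88.0 ± 9.27 to 1.17 ± 0.504 CPM, and Ccdc91 (chromosome 6, 147475828 to 147632612) from 39.7 ± 2.35 to 0.594 ± 0.138 CPM (SD, n = 4 each). These correspond to 71.1-fold and 64.4-fold lower levels. Among the genes that rose, Eda2r (chromosome X, 97333840 to 97377216), a receptor for ectodysplasin A2 and a p53 target, was 40.0-fold higher, at 15.8 ± 2.32 against 0.389 ± 0.0861 CPM (SD, n = 4 each). Prss56, a serine protease gene, was 15.3-fold higher at 141 ± 7.20 against 9.22 ± 1.19 CPM. The adjusted p was 1.35e-08 for Zfp518a, 1.62e-09 for Ccdc91, 1.35e-08 for Eda2r and 1.73e-09 for Prss56 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

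By the rule for named genes, the others with the largest rises were Mybpc1, Fgf17, Atp6v0c-ps2, Mrc1, F13a1, Nupr1, Ddr2 and Fndc3c1. Mybpc1, a myosin-binding protein gene, stood at 0.0649 ± 0.0167 CPM in WT and 4.36 ± 0.721 in Fbxl11-CKO. The collagen receptor gene Ddr2 went from 3.08 ± 0.534 to 42.6 ± 5.53 CPM, and the stress-induced gene Nupr1 was 15.2-fold higher. The growth factor gene Fgf17 went from 0.241 ± 0.135 to 5.86 ± 1.35 CPM, and Fndc3c1 from 0.513 ± 0.129 to 5.27 ± 0.818 CPM. Atp6v0c-ps2 is a processed pseudogene (1.69 ± 0.215 to 40.1 ± 14.4 CPM), and its counts are uncertain because reads may be shared with its parent gene. The macrophage genes Mrc1 and F13a1 rose mainly in Fbxl11-CKO replicate 1, which held 16.1 and 15.2 CPM against 0.98 to 3.91 and 0.481 to 2.04 in the other Fbxl11-CKO libraries. Without that library the log2 fold change of Mrc1 went from 4.34 to 2.96 and that of F13a1 from 4.10 to 1.99. The adjusted p of Mrc1, 0.00887 in edgeR's test, became 0.0996 without the WT libraries that hold Xist counts. The call for F13a1 held in 4 of the 8 fits that left out 1 library, with a highest adjusted p of 0.0831 in edgeR's test. By the same rule the others with the deepest falls were Rps4l, Hebp2, Map10, Capn5, Flywch2, Dhdh, Gpx7 and Tert. Rps4l, a transcribed processed pseudogene on the same chromosome as Ccdc91, is uncertain for the same reason as Atp6v0c-ps2. Dhdh, a dihydrodiol dehydrogenase gene, fell from 52.0 ± 2.07 to 1.70 ± 0.305 CPM. Capn5, a calpain gene, fell from 13.5 ± 2.62 to 0.347 ± 0.199 CPM, and Tert, the telomerase reverse transcriptase gene, from 6.32 ± 1.29 to 0.230 ± 0.156 CPM (SD, n = 4 each). The log2 fold change of Tert was -4.69, and -5.36 without Fbxl11-CKO replicate 4. Of the tested genes, 8725 (45.6%) had no overlap between the genotypes, where chance gives 2.86%. Without the WT libraries that hold Xist counts, 7852 genes were called, and 7211 of the 9799 (73.6%) were called in the same direction. With the noncoding share of each library as a covariate the calls numbered 6395.

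Rod and bipolar cell genes fell together. Of 26 tested rod genes, 25 fell and none rose, with a median log2 fold change of -1.91. Of 26 bipolar genes, 23 fell and none rose, with a median of -2.05. Gnat1, the rod transducin alpha subunit, fell from 97.3 ± 8.44 to 11.5 ± 2.40 CPM, and the retinol dehydrogenase gene Rdh12 from 247 ± 8.95 to 55.5 ± 7.48 CPM (SD, n = 4 each). Scgn, which encodes the calcium-binding protein secretagogin of cone bipolar cells, fell 15.1-fold, from 75.1 ± 14.1 to 4.94 ± 0.688 CPM. The rod transcription factor gene Nrl, chosen after its values were seen, fell 3.73-fold, from 1558 ± 187 to 418 ± 57.4 CPM. The bipolar genes Vsx1 and Grm6, also chosen after their values were seen, fell 12.9-fold and 11.3-fold. The rod gene that did not pass was Mef2c (log2 fold change 0.21), and the bipolar genes that did not were Lrit3 (0.16), Lhx4 (0.23) and Neurod4 (0.03).

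Most of the genes of photoreceptor precursors and of the first synapse that passed the test fell. Among 7 precursor genes 5 fell, with a median log2 fold change of -0.38. Crx, the transcription factor gene of both rods and cones, fell from 1780 ± 289 to 941 ± 57.6 CPM, while Otx2 (-0.07) and Prdm1 (0.02) did not pass the test. Among 23 synapse and phototransmission genes 15 fell and 2 rose, with a median of -0.67. Cplx4, a complexin of photoreceptor synapses, fell from 131 ± 12.2 to 36.6 ± 4.43 CPM (SD, n = 4 each), and Lrit1 fell 3.83-fold. Stx1a, a syntaxin of conventional synapses, rose from 24.6 ± 2.59 to 42.4 ± 4.68 CPM. Adjusted over the list alone, the counts were 0 up and 25 down for rods, 0 and 23 for bipolar cells, 0 and 5 for precursors and 2 and 15 for synapse genes. Against all other tested genes, limma's camera test with a preset correlation gave adjusted p = 1.14e-16 for the rod list, 1.42e-11 for bipolar, 2.76e-05 for synapse and 0.0522 for precursors. With an estimated correlation the adjusted p was 0.441, 0.465, 0.469 and 0.743 in the same order. The precursor list passed in 5 of the 8 fits without 1 library (WT replicates 1, 2 and 3, Fbxl11-CKO replicates 2 and 4), with a highest adjusted p of 0.103 in camera, and passed fry with adjusted p = 0.0105.

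**Figure D2:**
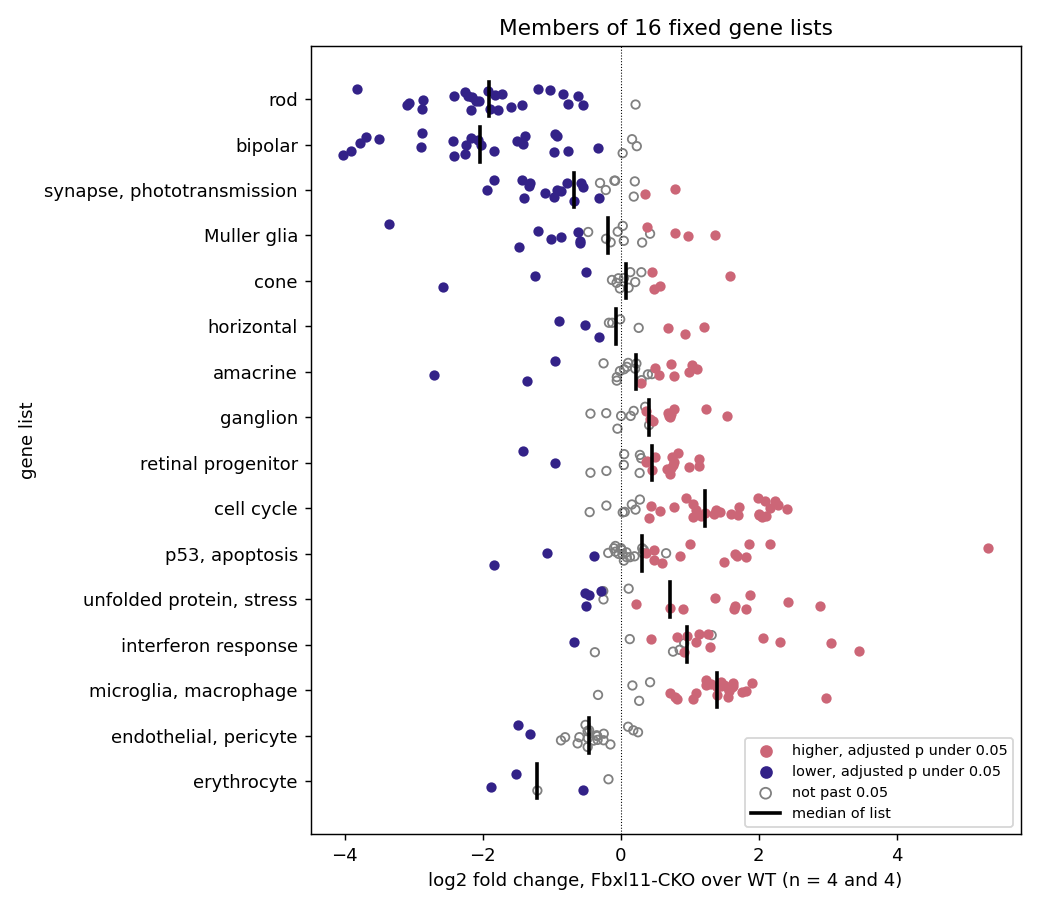
Log2 fold change (x axis, Fbxl11-CKO over WT, n = 4 libraries each) of every tested member of 16 gene lists (y axis), with a bar at each list's median. Filled points passed an adjusted p of 0.05 in edgeR's test, with 25 of 26 rod genes and 23 of 26 bipolar genes to the left of 0 and 26 of 33 cell-cycle genes to the right.

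The series title singles out late-born types, so their markers were compared with those of early-born types. The 72 late-born markers (rod, bipolar and Müller lists) had a median log2 fold change of -1.46, with 4 higher and 56 lower. The 67 early-born markers (cone, amacrine, horizontal and ganglion lists) had a median of 0.21, with 25 higher and 9 lower. Over all members, adjusted over the list alone, the counts were 4 and 56 and 25 and 9. The medians differed by -1.67, and limma's camera test between the lists gave p = 4.12e-15 with a preset and p = 0.00249 with an estimated correlation. Against all other tested genes the late-born list gave adjusted p = 1.14e-16 and the early-born list 0.0339 in camera. The adjusted p was 0.198 and 0.782 with an estimated correlation. The early-born call held in 3 of the 8 fits without 1 library, with a highest adjusted p of 0.0929.

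Genes of Müller glia, the remaining late-born type, moved in both directions. Of 20 Müller genes 4 rose and 8 fell, with a median log2 fold change of -0.18, which was -0.28 without Fbxl11-CKO replicate 1 and -0.07 without replicate 2. Dkk3, a secreted glycoprotein gene, rose from 256 ± 22.5 to 659 ± 159 CPM. The ABC transporter gene Abca8a fell 10.2-fold, from 31.2 ± 13.0 to 3.03 ± 0.603 CPM (SD, n = 4 each), and the carbonic anhydrase gene Car14 2.79-fold. Camera gave adjusted p = 0.260 for the Müller list, and 0.834 with an estimated correlation.

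In the cone, amacrine and horizontal lists genes moved in both directions, and in the ganglion list the genes that passed rose. In the cone list 4 of 16 genes rose and 3 fell. Ccdc136 rose from 199 ± 27.4 to 600 ± 66.5 CPM and the cone channel gene Cnga3 from 16.1 ± 2.58 to 22.4 ± 2.66 CPM. The green cone opsin gene Opn1mw fell from 4.57 ± 0.669 to 0.771 ± 0.311 CPM. In the amacrine list 8 of 23 genes rose and 3 fell. Gad2, an enzyme of GABA synthesis, rose from 28.5 ± 3.23 to 56.3 ± 6.47 CPM and Pax6 from 389 ± 12.6 to 645 ± 72.5 CPM, while the choline transporter gene Slc5a7, a marker of starburst amacrine cells, fell from 8.21 ± 1.79 to 1.25 ± 0.294 CPM. In the horizontal list 3 of 10 genes rose, with Onecut2 at 44.0 ± 6.10 and 101 ± 18.4 CPM, and 3 fell, with Prox1 at 332 ± 55.5 and 179 ± 21.8 CPM. In the ganglion list 10 of 18 genes rose and none fell, with a median of 0.41. Melanopsin (Opn4) rose from 2.84 ± 0.775 to 8.27 ± 1.99 CPM and Eomes from 13.3 ± 4.35 to 31.4 ± 5.33 CPM (SD, n = 4 each). The ganglion list stood highest in WT in replicate 3, at 0.36 above the WT mean (mean log2 CPM of the list). The counts adjusted over the list alone up and down were 4 and 3 for cone, 8 and 3 for amacrine, 3 and 3 for horizontal, 10 and 0 for ganglion and 4 and 8 for Müller genes. In limma's camera test the result was adjusted p = 0.00993 for the ganglion list, 0.104 for amacrine, 0.720 for cone and 0.866 for horizontal. The ganglion list had adjusted p = 0.782 with an estimated correlation, and the others 0.782, 0.907 and 0.907. The amacrine list passed camera in 1 of 8 fits without 1 library, that without Fbxl11-CKO replicate 4, with a highest adjusted p of 0.259. The cone list had a median of 0.08 and a mean of -0.04, and the horizontal list a median of -0.07 and a mean of 0.10, with the test upward in both. Over the fits without 1 library the horizontal median ran from -0.108 to 0.001.

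Proliferation genes and genes of retinal progenitors were higher in Fbxl11-CKO. Of 33 cell-cycle genes 26 rose and none fell, with a median log2 fold change of 1.22. Cyclin B1 (Ccnb1) rose 5.31-fold, from 7.00 ± 1.47 to 37.3 ± 3.30 CPM, and the mitotic kinesin gene Kif11 3.23-fold, from 16.7 ± 1.81 to 54.0 ± 2.86 CPM (SD, n = 4 each). Of 23 progenitor genes 14 rose and 2 fell, with a median of 0.45. The Notch ligand gene Dll3 rose from 4.73 ± 0.617 to 10.3 ± 1.12 CPM. Gadd45a fell from 18.7 ± 2.74 to 9.70 ± 0.896 CPM. Adjusted over the list alone, the counts were 26 and 0 for cell-cycle and 15 and 2 for progenitor genes. The camera test gave adjusted p = 1.42e-11 for the cell-cycle list and 0.00993 for the progenitor list, against adjusted p = 0.402 and 0.743 with an estimated correlation.

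Of 33 genes of p53 and apoptosis 13 rose, 3 fell and 17 did not pass, with a median log2 fold change of 0.31, which was 0.16 without WT replicate 2 or without Fbxl11-CKO replicate 3. After Eda2r, the strongest evidence was for Sesn2, a stress-induced sestrin gene, which rose from 12.8 ± 1.62 to 40.3 ± 5.34 CPM. The p53 targets Mdm2 (-0.08), Bax (0.01) and Ccng1 (-0.03), chosen after their values were seen, did not pass the test. The pro-apoptotic gene Bid fell from 10.7 ± 1.40 to 5.10 ± 0.824 CPM and Perp from 4.24 ± 0.774 to 1.19 ± 0.968 CPM. The log2 fold change of Perp was -1.84, and -2.61 without Fbxl11-CKO replicate 1. Among 6 genes of cyclin-dependent kinase inhibitors, Cdkn1a (p21) rose 3.50-fold, from 11.5 ± 2.42 to 40.3 ± 8.40 CPM, and Cdkn2c 1.92-fold. Cdkn1c (p57) fell from 23.2 ± 2.33 to 10.1 ± 2.39 CPM (SD, n = 4 each). Over all members, adjusted over the list alone, the counts were 13 and 3 for p53 and 2 and 1 for inhibitor genes. Camera gave adjusted p = 0.0145 for the p53 list, adjusted p = 0.743 with an estimated correlation. Without Fbxl11-CKO replicate 1 it was 0.0745. The inhibitor list gave 0.720, and 0.834 with an estimated correlation.

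**Figure D3:**
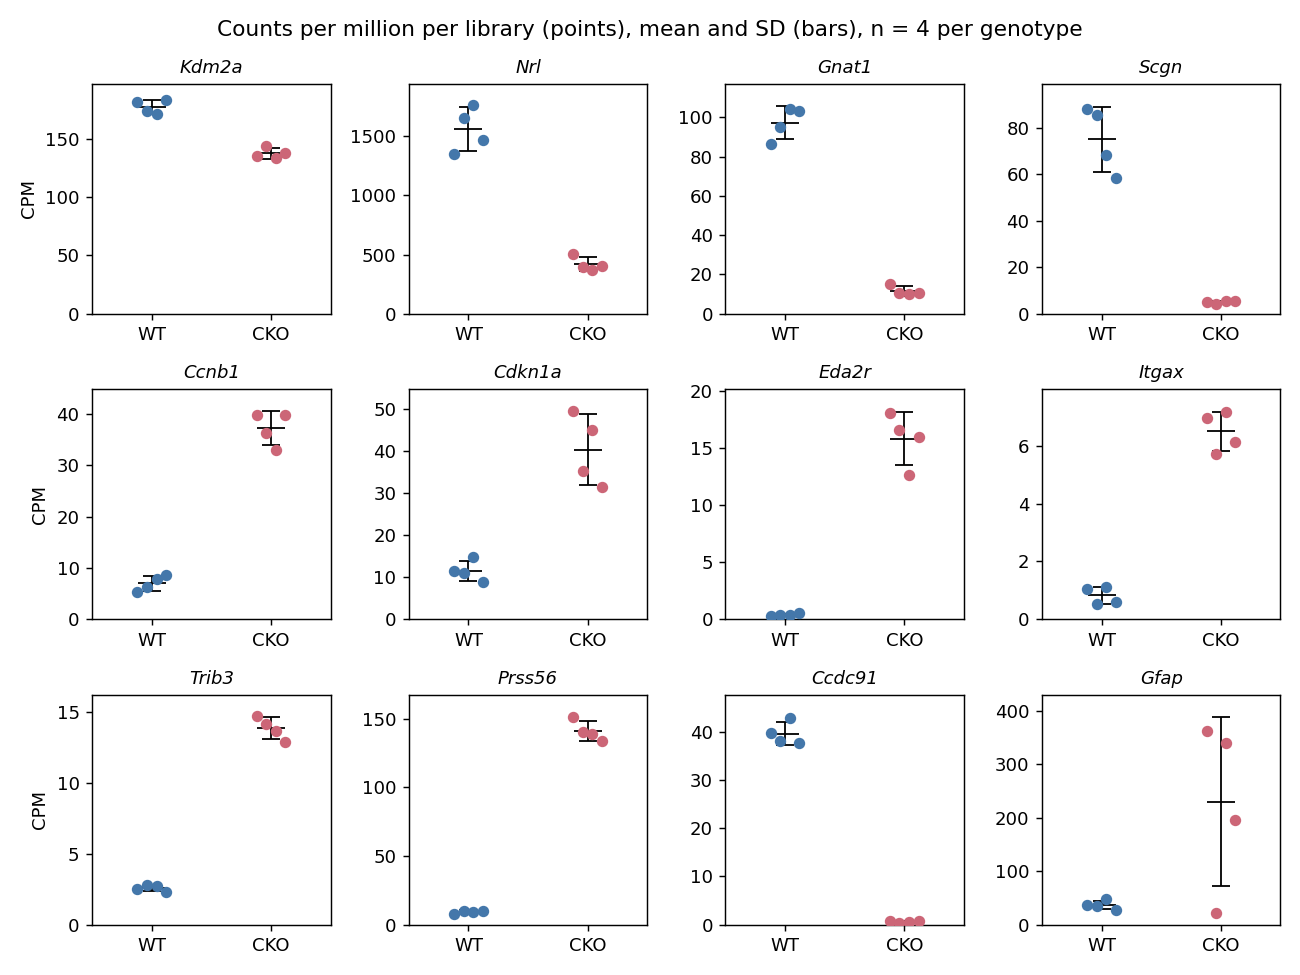
CPM (y axes, from 0) of 12 genes in each library (points, left to right by replicate number), with the mean and SD of each genotype, n = 4. Kdm2a falls from 177 to 137 CPM on average, and Gfap stands at 21.5 CPM in Fbxl11-CKO replicate 2, below the 4 WT libraries, and above them in the other 3 Fbxl11-CKO libraries.

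Genes of microglia and macrophages and of the interferon response were higher in Fbxl11-CKO. Of 28 microglia genes 24 rose and none fell, with a median log2 fold change of 1.40. Itgax, an integrin of activated microglia, rose 7.87-fold, from 0.825 ± 0.303 to 6.50 ± 0.678 CPM, and the lysosomal gene Cd68 2.91-fold, from 5.02 ± 0.557 to 14.6 ± 2.43 CPM (SD, n = 4 each). The homeostatic microglia genes P2ry12 (0.27) and Tmem119 (0.17), chosen after their values were seen, did not pass the test. Of 19 interferon genes 12 rose and 1 fell, with a median of 0.96. Usp18 rose from 0.325 ± 0.0770 to 1.63 ± 0.453 CPM and Irf9 from 11.5 ± 1.82 to 21.8 ± 2.73 CPM. H2-D1 fell from 29.0 ± 2.42 to 18.0 ± 8.25 CPM, a call that held in 1 of the 8 fits without 1 library, with a log2 fold change of -0.68, and -1.02 without Fbxl11-CKO replicate 1. The mean of the list (log2 CPM, relative to WT) was highest in Fbxl11-CKO replicate 1 for both, at 1.77 for microglia and 1.78 for interferon genes, against 0.74 and 0.37 in replicate 2. The counts adjusted over the list alone were 24 and 0 for microglia and 13 and 1 for interferon genes. In limma's camera test the result was adjusted p = 1.53e-07 for microglia and 0.00870 for interferon genes, and adjusted p = 0.743 and 0.782 with an estimated correlation.

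Genes of other non-neuronal cells and of gliosis moved in both directions or fell. Of 21 endothelial and pericyte genes none rose and 2 fell, with a median log2 fold change of -0.46, and its mean log2 CPM relative to WT was -2.83 in Fbxl11-CKO replicate 2 against -0.93 to 0.26 in the other Fbxl11-CKO libraries. The median was -0.13 without that library, -0.28 without WT replicate 3 or Fbxl11-CKO replicate 4, and -0.82 without Fbxl11-CKO replicate 3. Slco1c1, a transporter gene of blood vessels in the nervous system, fell from 4.69 ± 1.68 to 1.65 ± 0.592 CPM. Of 5 erythrocyte genes 3 fell, with Hbb-bs at 48.4 ± 19.5 and 13.0 ± 5.39 CPM. Among 19 genes of pigment epithelium, ciliary body and lens 9 fell and 2 rose, with Rpe65 at 15.5 ± 6.30 and 2.58 ± 1.41 CPM and the pigment-cell transcription factor gene Mitf at 5.05 ± 1.22 and 10.2 ± 0.960 CPM. That list stood 1.21 above the WT mean in WT replicate 3, and its median log2 fold change went from -1.25 to -0.61 without that library. Among 11 astrocyte and oligodendrocyte genes 5 rose and 2 fell. Aldh1a1 rose from 47.0 ± 12.5 to 121 ± 46.5 CPM and the myelin gene Mbp fell from 41.8 ± 2.54 to 15.3 ± 3.59 CPM (SD, n = 4 each). Among 13 gliosis genes 3 rose and 4 fell. Gfap stood at 36.6 ± 7.95 CPM in WT and at 363, 21.5, 340 and 195 CPM in Fbxl11-CKO replicates 1 to 4. Its adjusted p of 0.0258 in edgeR's test held in 1 of the 8 fits without 1 library, that without Fbxl11-CKO replicate 2. Hspb1 fell from 2.68 ± 0.449 to 0.546 ± 0.312 CPM and Nes from 54.0 ± 3.83 to 25.4 ± 11.4 CPM. Adjusted over the list alone, the counts up and down were 0 and 1 for endothelial, 0 and 3 for erythrocyte, 2 and 9 for pigment and lens, 5 and 2 for astrocyte and 3 and 4 for gliosis genes. The camera test gave adjusted p = 0.0715, 0.0939, 0.0546, 0.720 and 0.638 for these lists, and 0.834, 0.743, 0.818, 0.834 and 0.834 with an estimated correlation. Leaving out 1 library brought the endothelial list past camera in 3 of 8 fits (WT replicate 2, Fbxl11-CKO replicates 1 and 3), the pigment and lens list in 4 (WT replicates 1, 2 and 4, Fbxl11-CKO replicate 2) and the erythrocyte list in 1 (WT replicate 1), with highest adjusted p of 0.258, 0.135 and 0.149.

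Stress, immediate early, Notch and Wnt genes each moved in both directions. Of 17 genes of the unfolded protein and integrated stress responses 10 rose and 4 fell, with a median log2 fold change of 0.71. The pseudokinase gene Trib3 rose 5.35-fold, from 2.59 ± 0.227 to 13.9 ± 0.762 CPM, and asparagine synthetase (Asns) 3.51-fold, from 26.6 ± 5.07 to 93.5 ± 8.83 CPM. Atf4, whose protein drives the integrated stress response, fell from 406 ± 26.0 to 284 ± 28.7 CPM, and the chaperone gene Pdia4 from 155 ± 6.54 to 112 ± 18.4 CPM (SD, n = 4 each). The other members that fell were Hsp90b1 (-0.29), a chaperone gene, and Ppp1r15a (-0.51). Of 16 immediate early genes 7 rose and 2 fell. The neuronal activity genes Egr3 and Npas4 rose from 0.767 ± 0.266 to 3.66 ± 0.330 and from 1.67 ± 0.170 to 4.97 ± 0.954 CPM, while Ier3 fell from 24.5 ± 2.05 to 7.91 ± 2.18 CPM. In the Notch list 7 of 17 genes rose, with Notch1 1.67-fold higher, and 3 fell, with the ligand gene Jag1 2.55-fold lower. In the Wnt list 7 of 17 rose and 2 fell, and Notum, a secreted inhibitor of Wnt proteins, went from 0.374 ± 0.120 to 3.23 ± 1.52 CPM. Over all members, adjusted over the list alone, the counts up and down were 10 and 4 for stress, 7 and 2 for immediate early, 7 and 3 for Notch and 7 and 2 for Wnt genes. Camera gave adjusted p = 0.0145 for the stress list, adjusted p = 0.782 with an estimated correlation, and 0.0667 without Fbxl11-CKO replicate 1. The immediate early, Notch and Wnt lists gave adjusted p = 0.114, 0.268 and 0.150, and 0.782, 0.818 and 0.818 with an estimated correlation. Without Fbxl11-CKO replicate 4 the immediate early and Wnt lists passed, and over the 8 fits without 1 library their highest adjusted p was 0.233 and 0.402.

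In the chromatin, histone and germline lists genes moved in both directions. Of 15 genes of H3K36 demethylases and methyltransferases 3 rose and 6 fell. The H3K36 methyltransferase gene Nsd1 fell 1.97-fold, from 451 ± 19.4 to 229 ± 14.1 CPM, and the demethylase gene Kdm4c 1.53-fold, whereas Nsd2 rose 1.30-fold. Of 26 Polycomb genes 5 rose, with Cbx2 1.58-fold higher, and 10 fell, with Yaf2 1.69-fold lower. Of 9 tested germline genes 3 rose and 2 fell. Sycp2, a synaptonemal complex gene, rose from 3.68 ± 0.710 to 10.8 ± 3.92 CPM, and Tdrd7 fell from 345 ± 30.5 to 83.5 ± 8.79 CPM (SD, n = 4 each). Of 9 clustered histone genes 3 rose and 1 fell, the linker histone gene Hist1h1c, from 55.4 ± 14.6 to 27.9 ± 5.39 CPM. The counts adjusted over the list alone up and down were 3 and 6 for H3K36, 7 and 10 for Polycomb, 3 and 2 for germline and 3 and 1 for histone genes. In limma's camera test the result was adjusted p = 0.288, 0.711, 0.866 and 0.720 for these lists, and 0.782, 0.834, 0.907 and 0.834 with an estimated correlation. The Polycomb list had a median of 0.06 and a mean of -0.05, and the germline list a median of 0.38 and a mean of -0.02, with the test downward in both. Leaving out 1 library gave Polycomb medians of 0.01 to 0.11. Among 5 sex-linked genes Xist fell, 2952 ± 3613 against 7.09 ± 1.79 CPM, and the 4 Y-linked genes did not pass the test. The call for Xist, with adjusted p = 0.0460 in edgeR's test, held in 2 of the 8 fits without 1 library. Adjusted over the list alone, no sex-linked gene passed, and camera gave adjusted p = 0.176 (0.782 with an estimated correlation), with a list median of 1.01, a mean of -0.71 and an upward test. That median was 0.587 without WT replicate 3 and 1.735 without WT replicate 2. The 13 mitochondrially encoded genes were listed at 0 in all 8 libraries.

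In total 12 of the 31 tested lists passed camera with a preset correlation of 0.01, 8 upward and 4 downward. With an estimated correlation 0 lists passed, the lowest adjusted p being 0.198, and 3 had an unadjusted p under 0.05. The rotation test fry, which asks whether a list's genes move on balance one way without comparing them with other genes, passed 17 lists.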

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

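The tests of sex-linked counts and noncoding share in this part were chosen after the result was seen. The screen itself compared each library with the other 3 of its genotype, for named genes, list means and library measures. By Dixon's test 22 of 306 sets of 4 values held a library that stood apart, where chance gives about 1 in 20 sets, or 15.3.

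Fbxl11-CKO replicate 1 stood apart in 8 of them. It held more F13a1 (15.2 CPM against 0.481 to 2.04), Gnat1 (15.1 against 10.2 to 10.5), Lrit1 (112 against 81.1 to 84.1), Perp (2.62 against 0.507 to 0.833), Usp18 (2.31 against 1.37 to 1.47), Aldh1a1 (191 against 93.1 to 107) and Slc7a2 (52.6 CPM), and less Fgf17 (3.85 against 6.39 to 6.75 CPM). In Fbxl11-CKO replicate 4 Rpe65 stood at 4.67 CPM against 1.61 to 2.04. The astrocyte and oligodendrocyte list mean of Fbxl11-CKO replicate 2 was -0.81 against 0.39 to 0.57 (log2 CPM relative to the WT mean), and the amacrine mean of replicate 3 was 0.38 against -0.01 to 0.03.

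WT replicate 3 stood apart in the pigment, ciliary and lens list (1.21 against -0.46 to -0.33), the ganglion list (0.36 against -0.16 to -0.07), Bfsp2 (2.33 CPM), Lrat (3.92 CPM), Asns (34.2 CPM against 23.8 to 24.3) and Fgf17 (0.039 CPM). WT replicate 4 held less Sept4 (160 CPM against 166 to 167), Cdkn1c (19.8 CPM) and F13a1 (0.133 CPM) and more Egr3 (1.16 CPM), and WT replicate 2 more Ier3 (27.6 CPM).

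The libraries differ in sex-linked counts and in their noncoding share, and both could carry part of the 9799 calls. Without the WT libraries with Xist counts, 73.6% of the called genes were called again in the same direction, and with the noncoding share as a covariate 59.7% were. The first value argues against the sex-linked difference as the whole cause, since the bound written for a sole cause was under 10%. For the noncoding share the fit cannot decide, because the share follows genotype closely. It was 1.78, 1.79, 2.04 and 2.8% in WT replicates 1 to 4 and 2.3 to 3.45% in Fbxl11-CKO. Only WT replicate 4 lay inside the Fbxl11-CKO range, and Xist made up 0.697% of its counts. The genes that lost their call stay open, because the first fit has 2 WT libraries and the second 1 residual degree of freedom less.

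The 35 ways of parting the 8 libraries into 4 and 4 give each result a chance comparison, planned before the data were examined. The real split, with 9799 genes and 3231 of at least 2-fold, was the 1 split of 35 with as many in each count. Every other split gave 0 genes in edgeR's test, with 16 to 4761 genes at an unadjusted p under 0.05. Each other split puts both genotypes in each group, which widens the spread it is tested against and makes calls less likely. The splits therefore argue against chance for both counts only at 1 of 35, the smallest share they can give. The same holds for the late-born against early-born difference of 1.665, as large in 1 of 35 splits, with 1.003 the highest of the others. For the number of gene lists chance cannot be excluded. As many lists as the real 12 passed camera with a preset correlation in 15 of the 35 splits, and the highest other split passed 20. Splits with unequal shares of the genotypes keep part of their difference, so 15 of 35 is not a pure chance rate.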

How the results depend on the processing

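The fits without the 2 WT libraries with Xist counts and with the noncoding share as a covariate were chosen after seeing the data. Whether the replicate numbers pair the libraries stayed open. The correlations of same-numbered deviations were -0.005, 0.065, 0.22 and 0.332, and 2 of the 4 WT libraries correlated best with their own number. A replicate block called 10573 genes against 9799, of which 9616 were shared calls. Over the planned scalings, filters and tools at the same threshold the calls numbered 8842 to 10316, the 2-fold calls 2414 to 4286, and the log2 fold change of Kdm2a lay between -0.40 and -0.29. Leaving out 1 library gave 8419 to 10635 calls, 3041 to 3750 of at least 2-fold, 10 to 16 lists, a late-early difference of -1.80 to -1.62 and -0.40 to -0.35 for Kdm2a. Counts that moved by over 1.5 times were 3153 higher genes at an adjusted p of 0.01, 3167 lower genes against a 1.2-fold change, and 6395 genes with 3063 higher with the noncoding covariate; a stricter threshold or a lost degree of freedom is part of those settings. With an estimated correlation 0 lists passed. Upper-quartile scaling moved the median log2 fold change of all genes from 0.028 to 0.103 and the share of higher calls from 50.9% to 59%.

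Xist reversed to 1.97 without the 2 WT libraries that hold most of its counts. The fall is lost by construction, but the rise is not fixed by it. In lists that passed in neither fit, the direction of the camera test reversed, while the list median kept its sign except for gliosis and Müller genes, and the cause was not tested. The medians were horizontal -0.094 without a filter, histone -0.053 with a stricter one (0.00 in the comparison itself), gliosis 0.325 and sex-linked 0.976 in DESeq2, germline 0.35 with the block and 0.326 without the Xist libraries, and gliosis 0.005 and Müller 0.064 with the covariate. The direction also reversed without 1 library for germline (5 fits), gliosis (without Fbxl11-CKO replicate 2) and cone (without Fbxl11-CKO replicate 1), where over all such fits the medians ranged from 0.143 to 0.652, -0.149 to 0.284 and 0.001 to 0.119. Depth limits genes near the floor of 0.083 to 0.153 CPM, such as the Hox genes.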

Other observations

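The tests in this part on microglia, cell-cycle and blood genes and on the lowest rod or bipolar marker were chosen after the result was seen. So were those on Hox counts and on the CpG content of the higher genes. Those on the CpG content, linkage, length and GC content of the lower genes were not. The comparison of all called genes near Kdm2a with those elsewhere was not among the planned tests. Genes in the next paragraph were chosen after their values were seen.

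Among the 32 genes at least 8-fold higher with no overlap between genotypes (mean log2 CPM of at least 1) were Lin28b, whose RNA-binding protein blocks let-7 maturation, and the cationic amino acid transporter genes Slc7a2 and Slc7a3. Lin28b went from 3.46 ± 0.553 to 30.3 ± 7.17 CPM, Slc7a2 from 3.58 ± 0.410 to 35.1 ± 11.8 and Slc7a3 from 2.10 ± 0.570 to 18.7 ± 1.77 CPM (SD, n = 4 each). The 91 genes at least 8-fold lower by the same rule included Phyh, an enzyme of peroxisomal alpha-oxidation (42.4 ± 1.56 to 1.67 ± 0.650 CPM), and the meiotic genes Mlh3 (59.0 ± 4.16 to 3.88 ± 0.645), Hfm1 (13.2 ± 2.16 to 1.16 ± 0.387) and Terb1 (5.22 ± 0.635 to 0.523 ± 0.141 CPM). The 32 higher genes had a median CpG observed to expected ratio of 0.41 over the first 300 nt. That lay below the 95% range of 0.465 to 0.643 of random sets matched on Fbxl11-CKO expression (median 0.554, permutation p = 0.0014). The sets were not matched on WT expression or on gene type. Rod and bipolar markers had a median ratio of 0.419, so a low ratio was not particular to genes that rose. The genes named here had adjusted p between 7.83e-09 and 6.47e-07 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

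Hox genes lay below the filter of the main test. Their counts summed over 39 genes were 0, 0, 0 and 1 in WT replicates 1 to 4 and 14, 11, 7 and 5 in Fbxl11-CKO replicates 1 to 4. Of the 37 counts in Fbxl11-CKO, 15 were of Hoxb9, found in all 4 libraries, and 7 of Hoxd8. The share of counts on Hox genes differed with p = 0.0286 in a two-sided exact permutation test, the smallest p that 4 against 4 libraries allow. Without the filter the Hox genes with a count had a median log2 fold change of 1.55, against 0.156 for all genes with a count. Their adjusted p was 0.203 in camera. Only 11 Hox genes had a count in Fbxl11-CKO and 1 in WT, so this median repeats the counts above and adds no support. Genes with a count numbered 27262 to 28487 in the WT and 28326 to 30869 in the Fbxl11-CKO libraries. Other genes near the floor were not compared, so the rise may not be particular to Hox genes. Xist showed a second difference, among the libraries with Y-linked counts. It stood at 46 and 45 counts in WT replicates 1 and 2 and at 158 to 324 in Fbxl11-CKO, with a log2 fold change of 1.97 and adjusted p = 0.000608 in edgeR's test.

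The 91 genes at least 8-fold lower raise the question of what sets them apart. A candidate explanation from the biology of Kdm2a, whose zinc finger binds unmethylated CpG, is a CpG-rich 5′ end. Their median CpG observed to expected ratio over the first 300 nt was 0.55, below the 0.567 of 10000 random sets matched on WT expression but inside their 95% range of 0.515 to 0.616 (permutation p = 0.542), which leaves that open. Their positions argue against strain variation linked to Kdm2a as the cause for the whole set, with 1.1% of the genes within 20 Mb of it. Of tested genes with a mean log2 CPM of at least 1, 1.7% lay there. For chromosome 19 as a whole the shares were 5.5% and 3.2% (Fisher exact p = 0.215). Of all tested genes in the window 57.1% were called, against 51.2% elsewhere (Fisher exact p = 0.0426). Strain variants elsewhere in the genome were not tested. Within the set, some genes lay near each other. Ccdc91 and Rps4l start at 147475828 and 148354656 on chromosome 6, and Gpx7 and Echdc2 at 108400390 and 108165437 on chromosome 4. Dnaja4 and Cib2 start at 54698873 and 54544794 on chromosome 9. Whether the set clusters more than other genes was not tested. Length or GC bias is argued against by a median GC content of 50.3% (95% of matched sets 49.15 to 52.81) and a median length of 1789 nt (1233 to 1938). Loss of rod and bipolar cells may account for some of them. The lowest of those markers was Gng13 at -4.03, and 14 of the 91 fell below -4.55, or 2 of its standard errors lower. The standard errors of the 14 genes were left out of that threshold. Since a lost cell type sets no lower bound, such a loss cannot be told apart from other causes.

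Higher microglia and cell-cycle genes could follow from a smaller share of rods and bipolar cells, which would raise every other type alike. Relative to the mean of the amacrine, horizontal and ganglion lists, the microglia list was 0.97 higher in Fbxl11-CKO (log2). Its SD was 0.15 in WT and 0.44 in Fbxl11-CKO. The cell-cycle list was 0.97 higher (SD 0.17 and 0.10). Both argue against a smaller rod and bipolar share as the whole cause, if those reference lists stand for every other type. The reference lists themselves stood 0.10, 0.10 and 0.45 above the WT mean in Fbxl11-CKO. Other lists differed from them by -1.36 (erythrocyte), -1.24 (pigment, ciliary and lens), -1.10 (endothelial), -0.05 (astrocyte) and 0.69 (interferon). The progenitor list was 0.13 higher by the same measure (SD 0.20 and 0.09, exact permutation p = 0.314), so for its rise a smaller rod and bipolar share stays open. Blood carried into the Fbxl11-CKO libraries is argued against by the erythrocyte list, which was lower in each Fbxl11-CKO library than in any WT library, by -1.15 on average. More microglia, more transcripts per microglial cell and longer proliferation remain open as hypotheses, untested here, which counts of stained cells, sorted microglia and labelling of dividing cells would tell apart.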
